A study of Mus musculus with 6 samples.

How the data were processed

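RNA was measured in Melan-a cells, an immortalised line of pigmented mouse melanocytes of C57BL/6 origin, after transfection with an siRNA against Dicer (siDicer) or a control siRNA (siScr), with 3 samples in each group. Per the labels, cells were kept in medium with 200 nM of the phorbol ester TPA, 150000 cells were seeded per well, and 50 pmol of siRNA was given with a lipid reagent and magnetic particles. The time point is stated in more than 1 way: the titles and the design text give 48 h after transfection, while the treatment protocol describes a change of medium after 6 h and lysis 24 h after that. The design text calls the samples biological replicates, and the labels give each replicate number one cell passage in both groups, 47 for replicate 1, 54 for replicate 2 and 56 for replicate 3. The RNA integrity number was 10.0 in every sample, and 100 ng of total RNA went onto each Affymetrix Clariom D mouse array after biotin labelling, per the labels' protocols.

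The values are log2 signals per transcript cluster, deposited by the authors already on a common scale across arrays. Affymetrix Expression Console is named in the submitters' processing notes, without a version. The summarisation and normalisation method, the annotation release and the genome build are not given in the sources used here, so no coordinates are printed. That the scale is log2 was read from the values, which ran from 1.70 to 13.70 with array medians of 4.63 to 4.68. The centring is unknown beyond those medians. Scanner files were not used here, so the background correction could not be varied and signal over background could not be measured. The number of arrays limits the precision.

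The table held 16383 transcript clusters on 6 arrays, with no missing value, and the chromosome numbers in their identifiers ran from 1 to 4. Genes of other chromosomes were not analysed here. The platform's annotation paired 7676 clusters with 1 gene, 309 with several genes and 8398 with none, and only those with 1 gene were named. Symbols were brought up to date through the RefSeq gene table of the mouse, which changed 317 of them. The genes of all 7676 clusters were found in that table, and for 7660 clusters the chromosome in the identifier equalled the one listed there. Where a gene had more than 1 cluster, the one with the highest mean over all arrays was used. Of 52 such genes, the clusters of 38 differed between the groups in the same direction and those of 14 in opposite directions, and 0 of the genes named in the text were among them. Of 7623 genes, those whose mean signal lay under the 30th percentile (log2 4.15) were left out as dim, which left 5336 tested genes. The probes of microRNA and small nucleolar RNA genes can read primary, precursor or host transcripts as well as the short RNA itself.

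Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean signal), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are those of the moderated fit, and SDs are over the 3 arrays of a group. An exact permutation test of 3 against 3 arrays has 10 splits and cannot go below a two-sided p of 0.1. The design, 27 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested members (18 lists), the microRNA genes and the small nucleolar RNA genes with Snora or Snord symbols were tested with limma's camera at a preset correlation of 0.01, adjusted over those 20 sets. Camera with an estimated correlation and fry, which asks whether the genes of a set move one way on balance or, in its mixed form, change in either direction, were run beside it. Fry does not compare a set with other genes. Members of a list were also counted after adjustment over the list alone. The rule named the 10 largest rises and 10 largest falls that passed with non-overlapping groups, or all that passed if fewer, or the 5 smallest p-values in a direction where none passed, leaving out small RNA genes, pseudogenes, predicted genes and olfactory or vomeronasal receptor genes. It also named up to 4 members of each list by smallest p, up to 3 microRNA genes per direction, and Dicer1, Mitf, Itgav, Itgb3, Tyr, Kit, Ago2 and Drosha. Of the last set only Itgav had a value, and the others were not analysed here. For the keratinocyte and leukocyte markers only means are given. How many members of each list to name, within that limit, was settled after the values and their stability were seen, and members with differences near 0 were mostly left unnamed. The rule was applied a further time to the fit with passage as a block, and this and the naming of Tyrp1, of H2ac21, of single small nucleolar RNA genes and of their host genes were chosen after the values were seen.

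The replicate numbers pair the samples, since the labels tie each number to a passage shared by both groups. Over the tested genes, deviations from the group means correlated at 0.42 for replicate 1, 0.62 for replicate 2 and 0.07 for replicate 3, against -0.54 to 0.28 between different numbers. The first principal component, with 39.3% of the variance, set both arrays of passage 54 apart from the other 4. The second, with 26.7%, set the siDicer arrays (-4.99 to -4.54) apart from the siScr arrays (3.93 to 6.10). The fit without the block is the one fixed in advance, and values with passage as a block are given where they change a call. The block assumes that the effect of a passage adds to that of the siRNA.

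The scripts were tested on simulated data for siDicer against siScr, in 20 sets of 5336 genes of which 200 were changed. Without the block, 69.0% of genes changed by log2 0.5 and 98.0% of those changed by log2 1 were recovered, and 0.9% of calls were false. With the block, these values were 93.7%, 99.8% and 4.6%. The simulated passage effects were additive and, like the variances, came from the block fit, so the simulation could not test that assumption. Its share of false calls therefore does not carry over to genes called with the block in the real data. Simulated lists with no change gave 0 calls on average, but the simulated noise was drawn independently for each gene. In the real data the estimated correlation within a list was 0.72 for G1/S and 0.97 for interferon genes. The simulation therefore does not show how often such lists are called falsely. Alternatives covered the replicate block, the variance trend, robust variances, array weights, quantile normalisation, median centring, the dim filter, the averaging of clusters, and leaving out each array. A search of 3' untranslated regions for microRNA seed sites was not run, because no genome sequence was used here.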

Results

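Transcript levels were compared between Melan-a melanocytes transfected with siDicer and with siScr, 3 arrays each, to ask what lowering Dicer changes in the transcriptome. Dicer is the ribonuclease that cuts microRNA precursors into mature microRNAs. Array medians lay between log2 4.63 and 4.68, and pairs of arrays correlated at 0.993 to 0.997 over all transcript clusters. The targeted transcript, Dicer1, was not analysed here, so the data give no check of the knockdown or of the group labels. Differences of single genes are over all 6 arrays, and those of 40 of the 86 named genes moved by over 1.5 times when 1 array was left out. Leaving out 1 array also leaves 1 passage in only 1 group.

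Tmem131, a transmembrane protein that takes part in collagen secretion, fell in siDicer cells. Its log2 signal (transcript cluster TC0100002193.mm.1, chromosome 1) was 8.69 ± 0.026 in siDicer and 9.57 ± 0.052 in siScr (SD, n = 3), a 1.84-fold difference. The log2 change was -0.88 with a standard error of 0.064 (limma, adjusted p = 0.0039), and the differences at passages 47, 54 and 56 were -0.97, -0.83 and -0.84. Of 5336 tested genes it was the 1 that passed the threshold, and 0 genes passed in the upward direction. At an unadjusted p under 0.05 there were 454 genes, 245 higher and 209 lower in siDicer, where chance gives 266.8. In 770 genes, or 14.4%, the groups did not overlap, against 10% by chance. Snora41, a small nucleolar RNA gene, had the smallest p-value among higher genes (log2 0.78, limma, adjusted p = 0.0646) and did not pass. Leaving out small RNA genes, pseudogenes and predicted genes, Stk16, Sulf2, Tinagl1, Galnt3 and Itga8 followed, with log2 differences of 0.58, 0.43, 0.50, 0.49 and 0.99, none of which passed (limma, adjusted p from 0.0923 to 0.127). Array weights raised the count to 14 genes, 7 higher and 7 lower. Without siDicer replicate 3 the count was 0 and the limma adjusted p of Tmem131 was 0.0542, within a range of 0.00219 to 0.0542 over all alternatives, and without siScr replicate 2 the count was 2.

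With passage as a block, 94 genes passed, 61 higher and 33 lower in siDicer. Each had the same direction at all 3 passages, which this fit selects for. The largest rises and falls are given here for genes whose groups did not overlap, without small RNA genes, pseudogenes and predicted genes. The largest such rise was that of Itga8, the integrin alpha 8 subunit, at log2 0.99 ± 0.091 (SE, limma with passage as a block, adjusted p = 0.00642). F3, the tissue factor that starts coagulation, rose by 0.87, the adenylate kinase Ak5 by 0.65 and Npnt, nephronectin, a matrix ligand of integrin alpha 8, by 0.56. The others of the 10 largest such rises were B4galt5 (0.58) and Galnt3 (0.49), which are glycosyltransferases, the kinase Stk16 (0.58), the receptor Ror1 (0.56), the iron exporter Slc40a1 (0.50) and the matrix protein Tinagl1 (0.50).

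The largest fall with passage as a block was that of Kcnj13, an inwardly rectifying potassium channel, at log2 -1.43 ± 0.12 (SE, limma, adjusted p = 0.00642). Pmp2, a fatty acid binding protein of myelin, fell by 1.01 and Trp53inp1, a stress protein induced by p53, fell by 0.98. Ugcg, the glucosylceramide synthase, fell by 0.61 and the palmitoyltransferase Zdhhc21 fell by 0.55. The others of the 10 largest falls with non-overlapping groups were Tmem131 (-0.88), C1ql3 (-0.64), Pcmtd2 (-0.57), the retinoid receptor Rxrg (-0.54) and the nuclear exoribonuclease Xrn2 (-0.51). Of the 94 genes, 72 were protein coding (40 higher, 32 lower) and 15 were among the 113 tested genes that RefSeq types as small nucleolar RNA, all higher. The sizes ran from 0.33 to 1.43, and 734 genes had an unadjusted p under 0.05. The count was 5 without passage 47, 18 without passage 54 and 154 without passage 56, and 22 of 7623 genes passed when dim genes were kept in.

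**Figure D1:**
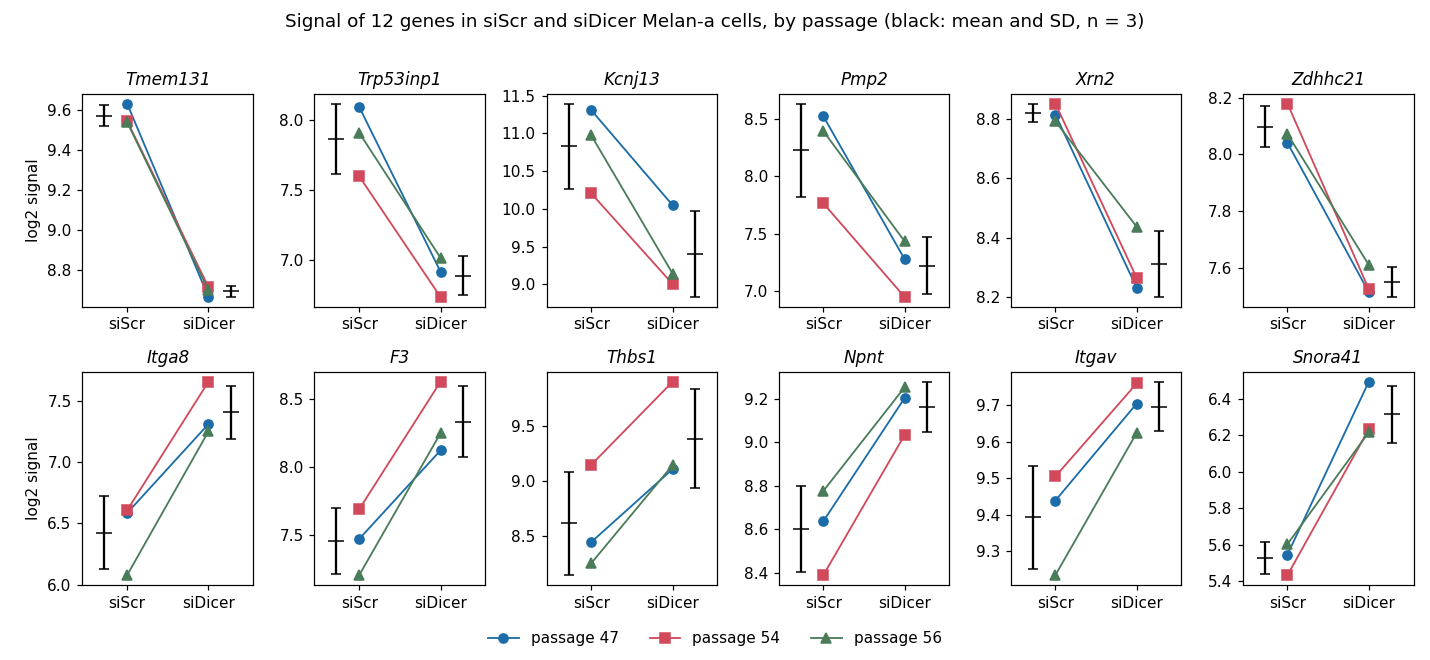
The log2 signal (vertical axis) of 12 genes is plotted for siScr and siDicer cells (horizontal axis), with a line joining the samples of each passage and, in black, the mean and SD of the 3 arrays of a group. Tmem131 lies at 9.57 in siScr and 8.69 in siDicer, and every line of Kcnj13 falls and every line of Itga8 rises although their passages start at different levels.

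Among genes that make, carry or use microRNAs, Xrn2, which degrades RNA from its 5' end in the nucleus, had the largest difference. It fell by 0.51 with passage as a block (limma, adjusted p = 0.0284) and did not pass without the block (adjusted p = 0.113). Ago3, an Argonaute protein that binds microRNAs, differed by -0.30 ± 0.065 (SE), Mov10 by 0.17 and the uridylyltransferase Tut4 by -0.13. Of 12 tested members 4 were higher and 8 lower, 0 passed over all genes, and 2 (Xrn2 and Ago3) passed adjusted over the list alone. The list mean of -0.087 did not pass with camera (limma, adjusted p = 0.0577, and adjusted p = 0.471 with an estimated correlation) and passed with fry (adjusted p = 0.0464). Camera also called the list after quantile normalisation (adjusted p = 0.0282), with array weights (adjusted p = 0.0489) and with dim genes kept in (adjusted p = 0.0366).

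The tested integrin genes were higher in siDicer as a group. Of 26 listed integrins 5 were tested, all of them alpha subunits, so the result does not cover beta subunits. All 5 were higher, by a mean of log2 0.36 and a median of 0.29, and Itga8 contributed most to the mean. Itga8 was at 0.99, the vitronectin receptor subunit Itgav at 0.30, Itga4 at 0.29, Itga10 at 0.16 and Itga6 at 0.063. Itga6 ranged from -0.12 to 0.23 over the passages. With 1 array left out Itga4 ranged from 0.023 to 0.55 and Itga10 from 0.063 to 0.22, with the lowest values without siDicer replicate 3 and siDicer replicate 2. Camera called the list (limma, adjusted p = 0.00111), and this was lost at adjusted p = 0.388 with an estimated correlation. By gene, 0 passed over all genes and 2 (Itga8 and Itgav) adjusted over the list alone, and with passage as a block 1 passed over all genes and 4 adjusted over the list alone.

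Genes of the extracellular matrix and focal adhesions were also higher as a group, 8 of 10 tested members, with a mean of log2 0.24. Thbs1, the matrix glycoprotein thrombospondin 1, rose by 0.77 and Lamc1, the laminin gamma 1 chain, rose by 0.42 with passage as a block (limma, adjusted p = 0.00642 and 0.0304). Lama5, another laminin chain, differed by 0.35 and the integrin-binding protein Tln1 by 0.12, and neither passed. Camera called the list (limma, adjusted p = 0.00111), and this was lost at adjusted p = 0.54 with an estimated correlation. By gene, 0 passed over all genes and 1 (Lamc1) adjusted over the list alone, and with passage as a block 2 and 5. Without siDicer replicate 2 the list mean was 0.12 and without siScr replicate 3 it was 0.16.

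Genes of the G1/S transition and of DNA replication were higher in siDicer in 11 of 11 tested members, by a mean of log2 0.29. E2f1, a transcription factor of S-phase entry, was higher by 0.33 ± 0.076 (SE), the replication factors Gins1 and Mcm10 by 0.37 and 0.34, and Dtl, part of a replication-linked ubiquitin ligase, rose by 0.45 with passage as a block (limma, adjusted p = 0.0299). Camera called the list (limma, adjusted p = 1.58e-06), and this was lost at adjusted p = 0.508 with an estimated correlation. By gene, 0 passed over all genes and 1 (E2f1) adjusted over the list alone, and with passage as a block 1 and 10. The mean shift was 0.44, 0.17 and 0.26 at passages 47, 54 and 56, and without siScr replicate 1 the list mean was 0.16.

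The list of G2/M and mitosis genes did not pass. Its 17 tested members had a mean difference of 0.015 (camera, limma, adjusted p = 0.654), a sign that turned to -0.0035 after quantile normalisation. The kinetochore motor Cenpe differed by -0.39 and the checkpoint kinase Bub1b by 0.18, with 0 members passing over all genes or adjusted over the list alone, and 1 (Cenpe) adjusted over the list alone with passage as a block. Camera called the list in opposite directions without siScr replicate 1 (mean -0.10, adjusted p = 0.036) and without siScr replicate 3 (mean 0.090, adjusted p = 0.0304). The mean was -0.076 without siDicer replicate 3, 0.077 and 0.043 without siDicer replicates 1 and 2, 0.055 without siScr replicate 2, -0.0058 with array weights and 0.040 after median centring.

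Pigment genes did not pass as a group. Of 7 tested members 2 were higher and 5 lower, with a mean of -0.15 (camera, limma, adjusted p = 0.437). The cystine transporter Slc7a11 differed by -0.59, but the passages gave -1.39, -0.32 and -0.067. Hps3, a factor of melanosome biogenesis, and Slc24a5, a melanosomal exchanger, each differed by -0.25, and were the 2 that passed adjusted over the list alone with passage as a block, where 0 passed without it. Tyrp1, a melanosomal enzyme with a log2 level of 12.81 in siDicer and 12.86 in siScr, differed by -0.049. The list mean ranged from -0.28 without siScr replicate 2, where camera called it (limma, adjusted p = 0.0184), to -0.073 without siDicer replicate 2 and -0.019 without siScr replicate 1, and was -0.23 with array weights. With 1 array left out Hps3 ranged from -0.41 to -0.12 and Slc24a5 from -0.43 to -0.078, in both cases between siScr replicates 2 and 1, and Slc7a11 was at -0.23 without siScr replicate 1.

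Transcription factors and survival genes of melanocytes had 4 higher and 4 lower members of 8, with a mean of 0.025 and a median of -0.0039 (camera, limma, adjusted p = 0.858). With 1 array left out the mean ran from 0.008 without siDicer replicate 1 to 0.045 without siScr replicate 1, with 0.039 without siDicer replicate 3, 0.016 without siScr replicate 2 and 0.013 without siScr replicate 3, and it was 0.050 after median centring. Lef1, a transcription factor of Wnt signalling, rose by 0.38 with passage as a block (limma, adjusted p = 0.034). Creb1 differed by -0.13 and Pax3 by -0.12. Over all genes or adjusted over the list alone 0 passed without the block, and 1 (Lef1) in both counts with it. Of the neural crest and dedifferentiation genes 3 of 4 were higher, with a mean of 0.12. Nes, the intermediate filament nestin, rose by 0.37 with passage as a block (limma, adjusted p = 0.0376), and Cd44 differed by 0.16. Without the block 0 passed in either count.

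Known target genes of microRNAs went in both directions. Of 9 tested let-7 targets 5 were higher and 4 lower (mean 0.084, camera, limma, adjusted p = 0.572). Their mean was 0.023 without siDicer replicate 2, 0.13 without siScr replicate 2 and 0.14 with array weights. Among them Fign rose by 0.36 and Tgfbr1, a receptor for TGF-beta, fell by 0.46 with passage as a block (limma, adjusted p = 0.0376 and 0.034), while Plagl2 differed by 0.24. Without the block 0 members of the 3 target lists passed over all genes. Fign and Tgfbr1 were the 2 let-7 targets that passed adjusted over the list alone, and with passage as a block 3 passed in both counts. Of 15 targets of the miR-17 and miR-92 families 8 were higher and 7 lower (mean 0.042, adjusted p = 0.572 with limma's camera), with E2f2 at 0.24 and Rgl1 at -0.21, and 1 (E2f1) passed adjusted over the list alone, and 2 (with Itgav) with passage as a block. The mean of this list was 0.023 without siScr replicate 2 and 0.067 after median centring. Of 14 targets of miR-29, miR-30, miR-26, miR-21, miR-211 and miR-204, 7 were higher and 7 lower, with a mean of 0.033, a median of -0.017 and an upward camera test (limma, adjusted p = 0.669). The mean turned to -0.029 without siDicer replicate 2 and to -0.0005 without siScr replicate 3, and was 0.081 without siDicer replicate 3, 0.060 without siScr replicate 2, 0.080 with array weights and 0.058 after median centring. Spry1 differed by 0.30 and Mcl1 by -0.17, and 1 (Lamc1) passed adjusted over the list alone, and with passage as a block 1 over all genes and 3 (with Spry1 among them) adjusted over the list alone. Fry found members changed in either direction among the let-7 targets and the miR-17 and miR-92 targets (limma, adjusted p = 0.0018 for each) and not among the last list (adjusted p = 0.222). The same fry test passed for genes of the microRNA pathway, TGF-beta, p53 targets and integrins (limma, adjusted p = 0.0018, 0.0030, 0.017 and 0.026). It was thus not particular to microRNA targets, and Tgfbr1 and Itgav are also members of the TGF-beta and integrin lists.

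Genes of the unfolded protein and integrated stress responses were lower in siDicer, 7 of 8 tested members, by a mean of -0.27. The largest difference was that of Slc7a11 (-0.59), which is also a member of the pigment list, and the 1 higher member was at 0.072. Chac1, a glutathione-degrading enzyme, differed by -0.44 ± 0.15 (SE), the pseudokinase Trib3 by -0.50 and Sesn2, a stress-induced regulator of growth signalling, by -0.43, and 0 members passed over all genes or adjusted over the list alone, with or without the block. Camera called the list (limma, adjusted p = 0.0206), and this was lost at adjusted p = 0.508 with an estimated correlation. The mean shift was -0.56 at passage 47, against -0.16 and -0.093 at passages 54 and 56. The call was lost with array weights (adjusted p = 0.116) and without siDicer replicate 3 (adjusted p = 0.101), and without siScr replicate 1 the mean was -0.12, with Chac1 at -0.26, Trib3 at -0.11 and Sesn2 at -0.22.

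TGF-beta and mesenchymal genes were lower in 7 of 9 tested members, with a mean of -0.12. Tgfbr1 differed by -0.46, and Id3 and Id1, inhibitors of basic helix-loop-helix factors, by -0.30 and -0.26. Camera called the list (limma, adjusted p = 0.039), and this was lost at adjusted p = 0.529 with an estimated correlation and at 0.0793 with passage as a block. By gene, 0 passed over all genes and 1 (Tgfbr1) adjusted over the list alone, and with the block 1 and 3. Without siDicer replicate 1 the limma adjusted p was 0.132 and the mean -0.078, without siDicer replicate 3 the adjusted p was 0.157, and without siScr replicate 2 it was 0.276 and the mean -0.076, while without siDicer replicate 2 the mean was -0.19. With array weights the adjusted p was 0.225 and the mean -0.069.

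Of 10 tested p53 targets 5 were higher and 5 lower (mean -0.13, camera, limma, adjusted p = 0.572). Trp53inp1, the member with the largest difference, was the 1 that passed adjusted over the list alone, and with passage as a block it passed in both counts, while Cdkn2b, a cell cycle inhibitor, differed by 0.12. Of 7 lysosomal genes 3 were higher and 4 lower (mean -0.088, adjusted p = 0.774 with limma's camera). Atp6v0d2, a subunit of the proton pump, fell by 0.69 with passage as a block (limma, adjusted p = 0.0304), and Ppt1 differed by 0.10. The lysosomal mean was -0.043 without siScr replicate 3, -0.056 without siDicer replicate 2, -0.16 without siScr replicate 2 and -0.15 with array weights.

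Interferon-stimulated genes had 2 higher and 5 lower members of 7, with a mean of -0.12 (camera, limma, adjusted p = 0.669). Gbp7, a guanylate-binding GTPase, fell by 0.58 with passage as a block (limma, adjusted p = 0.0252), and Gbp3 differed by -0.18. The direction of the list was not stable. Without siDicer replicate 2 camera called it as lower (mean -0.46, limma, adjusted p = 0.00311), while its mean was above 0 without siDicer replicate 1 (0.12), without siScr replicate 2 (0.15) and with array weights (0.17). It was -0.036 without siDicer replicate 3, -0.29 without siScr replicate 1 and -0.23 without siScr replicate 3. Of 4 inflammatory genes 1 was higher and 3 lower (mean -0.10). The adhesion molecule Vcam1 fell by 0.37 with passage as a block (limma, adjusted p = 0.033), and Traf1 differed by -0.060. In both lists 0 members passed without the block, over all genes or adjusted over the list alone.

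Small nucleolar RNA genes, whose products guide the modification of other RNAs, were tested as the class of genes with Snora or Snord symbols, of which 14 of 14 were higher in siDicer, by a mean of log2 0.49. Over all 113 tested genes of that RefSeq type, 75 were higher and 38 lower, with a mean of 0.14 and a median of 0.061. Snora41 was higher by 0.78 ± 0.090 (SE), Snora16a by 0.84 ± 0.23, Snord17 by 0.73 ± 0.19 and Snord87 by 0.47 ± 0.12. Camera called the class (limma, adjusted p = 1.49e-13), and this was lost at adjusted p = 0.471 with an estimated correlation. By gene, 0 passed over all genes and 10 adjusted over the list alone, and with passage as a block 7 and 14. The mean shift was 0.53, 0.60 and 0.33 at passages 47, 54 and 56.

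The 132 tested microRNA genes did not pass as a class, with 70 higher, 62 lower and a mean of log2 0.0017 (camera, limma, adjusted p = 0.858). The class sign turned to -0.0069 when genes under the 50th percentile were left out, and without siScr replicate 2 the class passed (mean 0.049, limma, adjusted p = 0.0184). Leaving out any other array gave means from -0.030 (without siScr replicate 3) to 0.018 (without siDicer replicate 1), array weights gave 0.036 and median centring 0.027. By gene, 0 passed over all genes or adjusted over the list alone. With passage as a block Mir181a-2 rose by 0.60 and Mir350 fell by 0.42 (limma, adjusted p = 0.0284 and 0.0376). Mir103-2 differed by 0.40, Mir7669 by 0.19, Mir695 by -0.21 and Mir7009 by -0.21, and none of these passed. Of 6 tested host transcripts of microRNAs 4 were higher (mean 0.085, or 0.054 with array weights, adjusted p = 0.378 with limma's camera), with Gpc1 at 0.40 (0.22 without siDicer replicate 1) and Nfyc at 0.13. Without the block 0 passed in either count, and with it 1 (Gpc1) passed adjusted over the list alone.

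**Figure D2:**
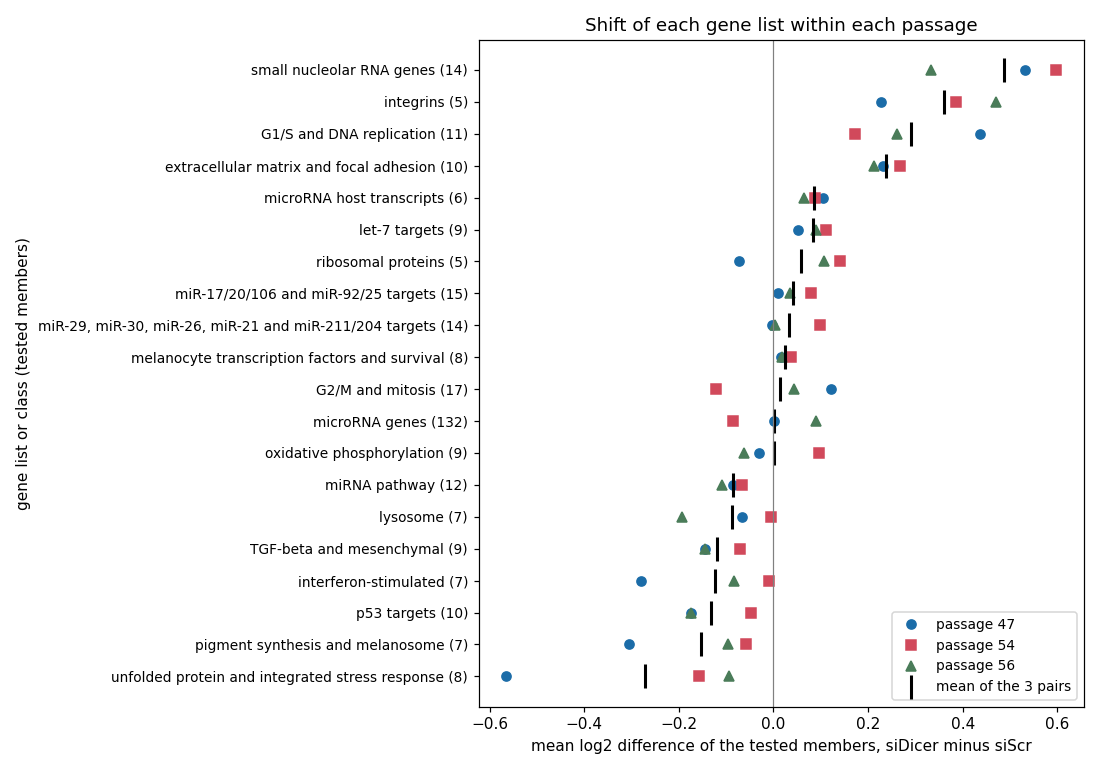
For each gene list or class with at least 5 tested members (vertical axis, number of members in brackets), symbols give the mean log2 difference between siDicer and siScr (horizontal axis) within each passage, and the black bar gives the mean of the 3 passages. By the mean of the 3 passages, the 14 Snora and Snord genes lie farthest to the right, at 0.49, and the stress response list farthest to the left, at -0.27.

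Genes of general metabolism and markers of other cell types were also measured. Of 5 ribosomal protein genes 4 were higher (mean 0.059, limma's camera, adjusted p = 0.326), with Rps20 at 0.13 and Rpl22 at 0.081, and without siScr replicate 1 the list passed (mean 0.10, adjusted p = 0.0321), while its mean was 0.035 and 0.036 without siScr replicates 2 and 3. Of 9 genes of oxidative phosphorylation 6 were higher (mean 0.001, limma's camera, adjusted p = 0.774), with Sdhb at 0.14 and Ndufb3 at -0.18. That mean turned to -0.013 after quantile normalisation and to -0.030 with array weights, was 0.026 after median centring, and ran from -0.045 without siScr replicate 2 to 0.033 without siScr replicate 3. Of 3 cholesterol synthesis genes 2 were higher (mean 0.033), with Hsd17b7 at 0.079. Among markers of other cell types, 4 fibroblast genes had a mean difference of 0.017 (Dpt at -0.053, Postn at 0.18), 2 keratinocyte genes -0.0043, 1 leukocyte gene -0.0079 and 2 endothelial genes 0.13, with Eng at 0.29 ± 0.46 (SE). In these lists 0 genes passed over all genes or adjusted over the list alone, and with passage as a block 1 (Eng) passed adjusted over the list alone. The lists of replication-dependent histones and Schwann cell markers had 0 tested members. H2ac21, a histone gene outside that list and named after its values were seen, rose by 0.33 with passage as a block (limma, adjusted p = 0.0481).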

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

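Transcript clusters without a single gene name took no part in the comparisons of named genes, and the test of them was chosen after the named genes had been seen. Of 8707 such clusters 6095 were bright enough to test, and limma called 0 without a block (306 at an unadjusted p under 0.05, where chance gives 304.8) and 1 with passage as a block. This cluster, TC0400002276.mm.1 of chromosome 4, differed by log2 -0.89 ± 0.095 (SE, limma with passage as a block, adjusted p = 0.0433; without the block, adjusted p = 0.733). The differences at passages 47, 54 and 56 were -0.91, -0.71 and -1.05. Its gene is not named here and no explanation was tested.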

How the results depend on the processing

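Alternatives with the replicate block together with another change, the test of all transcript clusters and the RefSeq definition of small nucleolar RNA genes were chosen after seeing the data. The count of 1 gene held for all alternatives fixed in advance except the replicate block (94 genes), array weights (14) and leaving out an array (0 to 2, with 0 without siDicer replicate 3 and 2 without siScr replicate 2), and all clusters also gave 1. With the replicate block the count was 101 without the trend, 125 with robust variances, 105 after quantile normalisation, 104 after median centring (75 higher, 29 lower), 22 with no dim filter, 143 with the 50th percentile filter, and 5, 18 and 154 without replicates 1, 2 and 3, of which 5, 17 and 84 were among the 94. Preset camera called 5 lists, an estimated correlation 0, fry 1 (6 lists in its test of change in either direction), the replicate block with an estimated correlation 0, and leave-one-out 3 to 7. The replicate block called 4 lists, losing TGF-beta, and brought 36 of the 86 named genes past the threshold. The naming rule had also been applied to that fit, so the count of 36 is in part fixed by the choice of genes. Over 15 alternatives per named gene (14 for 6 genes that the 50th percentile filter removed), 1228 results were the same, 48 newly passed, 1 no longer passed (Tmem131 without siDicer replicate 3) and 7 changed sign in 4 genes. The same here means the same sign and the same side of the threshold. Only Tmem131 passed in the main fit, so nearly all of the 1228 were genes that still did not pass. Which genes to name was partly settled after their stability was seen, so the tally does not stand for genes at large. In 40 of the 86 the difference moved by over 1.5 times with 1 array left out. The changes of sign were in Tyrp1 (-0.093 to 0.015 with an array left out), Eng (-0.21 to 0.69), Postn (-0.016 to 0.43) and Gbp3 (-0.52 to 0.061, and 0.10 with array weights).

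Means of lists near 0 also changed sign. With array weights these were G2/M (-0.0058), interferon (0.17) and oxidative phosphorylation (-0.030); after quantile normalisation G2/M (-0.0035) and oxidative phosphorylation (-0.013). Leave-one-out ranges were -0.029 to 0.081 for the miR-29 group of targets, -0.10 to 0.090 for G2/M, -0.46 to 0.15 for interferon and -0.045 to 0.033 for oxidative phosphorylation. The microRNA class was at -0.0069 with the 50th percentile filter and at -0.030 to 0.049 with an array left out, passing without siScr replicate 2. The causes were not tested. The seed-site search and its alternatives, and the alternatives for Dicer1, were not run. Signal over background was not used here, so what it limits was not tested.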

Other observations

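In this part, the comparison of passages, the tests of small nuclear RNA genes on distinct values above the 50th percentile and of small nucleolar RNA genes by RefSeq type, the separation of genes without a tested host, the test of the G1/S genes against the G2/M genes, the single-array tests of G1/S genes and Tmem131, and the weighing of an off-target effect were chosen after the results were seen. Interferon-stimulated genes separated the passages, whatever the siRNA. Their mean log2 signal was 8.28 and 8.29 on the arrays of passage 54 and 7.12 to 7.52 on the other 4. All 7 tested members were higher at passage 54, among them Ifi204 by 1.39, Ifih1, a sensor of double-stranded RNA, by 1.04, and Gbp7 by 0.93. The pigment list was lower on the passage 54 arrays (8.45 and 8.51, against 8.65 to 9.03), as was the lysosome list (7.66 and 7.66, against 7.70 to 7.90). The TGF-beta list was higher there (8.05 and 8.12, against 7.83 to 8.004), as were the let-7 targets (6.85 and 6.96, against 6.70 to 6.79) and the miR-29 group of targets (6.96 and 7.06, against 6.84 to 6.91). The other 14 sets overlapped, and differences between passages were not tested.

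Among gene types, 111 of 126 tested small nuclear RNA genes were higher in siDicer, but with a median of log2 0.11, and 108 of the 126 had distinct values, since some clusters repeat the values of others. By the RefSeq type, 75 of 113 small nucleolar RNA genes were higher, with a median of 0.061, and 15 rose with passage as a block.

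The higher Snora and Snord genes were weighed against 2 technical or indirect sources. For better recovery of all short RNAs in the siDicer extracts, a bound of 0.22 was set for the small nuclear RNA genes. This bound and the others below are 50% of the median rise to be explained, a share chosen here and not measured. Small nuclear RNA genes above the 50th percentile had a median of 0.11 (95% bootstrap interval 0.098 to 0.13), under the bound of 0.22. The bootstrap intervals given here resample genes and hold no spread between arrays, and the bounds are taken without error. Better recovery as the whole source for these 14 genes is therefore not decided. For all bright small nucleolar RNA genes by RefSeq type, better recovery cannot be told apart either. The median of the small nuclear RNA genes exceeded the matching bound of 0.094 by 0.018 (95% bootstrap interval -0.037 to 0.067). For higher host transcripts the bound was a median of 0.24, and the 6 tested hosts had 0.12 (95% bootstrap interval -0.021 to 0.16). For the 8 genes they hold, that median was under the bound, but the same limit of the interval leaves this source undecided. For the other 6, Snora16a among them, no host was tested and this source cannot be told apart. An effect of lowering Dicer on these RNAs stays open and was not tested, and the correlation within the class leaves the class call itself open.

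For the G1/S genes, the mean shift was upward at all 3 passages, the smallest being 0.17 and the largest 0.44. Without siScr replicate 1 the list mean was 0.16. The list was followed up because it had been called as higher, which favours upward shifts at every passage. Whether a single passage is the main source is therefore not decided. A larger share of cycling cells cannot be told apart. The G2/M mean shift plus 2 standard errors over the passages was 0.16, above a bound of 0.14. That bound was chosen from the G1/S mean shift, in the way used for the small nucleolar RNA genes. The G1/S shift exceeded the G2/M shift by 0.31, 0.29 and 0.22 at the 3 passages, a mean of 0.28 ± 0.051 (SD). An effect of lowering Dicer on S-phase entry stays open and was not tested.

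Tmem131 fell at all 3 passages, and the smallest of the falls was -0.83. It was picked as the 1 gene that passed, which favours falls of like size. Without siDicer replicate 3 its limma adjusted p was 0.0542. With any 1 array left out its log2 change stayed between -0.90 and -0.85, so the size of the fall did not rest on a single array. Only its place at the threshold changed without siDicer replicate 3. Pairing of the siRNA with Tmem131 mRNA cannot be told apart from an effect of Dicer, because the log2 change of -0.88 comes from 1 siRNA and no other siRNA against Dicer was among the samples.

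The 6 arrays can be split in 10 ways into 3 and 3, too few for a share under 0.05. The real split gave 1 gene and the highest of the others 0. With passage as a block, 4 splits part all 3 pairs, again too few; the real one gave 94 genes and the highest other 0. For lists called by preset camera, 3 of the 10 splits gave as many as the real 5, and the highest other, siDicer 1 with siDicer 3 and siScr 3 against the rest, gave 8. That split sets the array pair of passage 56 with siDicer replicate 1.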
